A study of Mus musculus with 8 samples.

How the data were processed

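Gene expression was measured by RNA sequencing in 8 libraries of cultured mouse pancreatic cancer cells, 2 from each of the groups PBS, ATEV, NTEV and DNase-treated ATEV. Total RNA was extracted with a column kit and made into stranded mRNA libraries, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, TopHat2 2.0.11, TopHat, Cufflinks 2.1.1 and the mouse build mm9, with no role or order. The counter, its strand setting and the annotation are not given in the sources used here. The values used are whole-number gene counts as deposited, in a table of 42687 genes keyed by Ensembl identifiers, with 1 column per library. A symbol was matched for 42250 identifiers from a mouse annotation (GENCODE M21) that was used for names, gene classes, transcript GC content and sequence properties only, and no coordinates were taken from it. The table holds no genes of the mitochondrial genome. Because the strand setting is not stated, values of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies, pseudogenes among them.

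Group and replicate of each library came from its label. The replicate numbers 1 and 2 name libraries and were not used to pair them. Replicates were compared before use: over genes with at least 20 counts the chi-square statistic per gene between the libraries of a group was 39.3 with PBS, 145 with ATEVs, 92.3 with NTEVs and 101 with DNase-treated ATEVs, so no pair agreed within sampling noise as a library deposited again would, and each was counted on its own. This does not show that they came from separate cultures.

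Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on expression by group, which left 15197, and scaled by the trimmed mean of M-values (TMM). A quasi-likelihood model with a mean per group was fitted over all 8 libraries, which share the estimate of the spread and leave 4 residual degrees of freedom. The common biological coefficient of variation was 0.226. The 5 comparisons were ATEV, NTEV and DNase-treated ATEV each against PBS, ATEV against NTEV, and DNase-treated against untreated ATEV. P-values were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. CPM values are TMM-scaled counts-per-million, given as mean ± SD over the 2 libraries of a group. SE is the standard error of a log2 fold change. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group and written as a lower bound, and with 1 to 3 counts the ratio carries a 95% exact counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

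A set of 30 gene lists was written down, with the tests, most of the alternatives and the rule for named genes, before the data were examined. The lists covered class I and class II antigen presentation, interferon responses, nucleic acid sensing, ligands of immune cells, NF-kB targets, tumour cell state, cell cycle, stress, metabolism and signalling, and markers of T cells, of myeloid and B cells, and of fibroblasts and endothelium. Each list with at least 5 tested members was tested with camera (limma 3.58.1) with a correlation preset at 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. Members called were counted over all genes tested and adjusted over the list alone. Some genes stand in more than 1 list. Genes were named by a fixed rule. In each comparison it took the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean log2 CPM of at least 1 and both libraries of a group above both of the other, leaving out predicted or unnamed gene models. It added up to 4 members with the smallest p of each list described, and H2-K1, H2-D1, B2m, Tap1, Psmb8, Nlrc5 and Cd274 in every comparison. Some genes that the rule takes are not reported here. Genes named outside this rule are values of members already described or are said to have been chosen after their values were seen.

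Overlaps between the comparisons that share the PBS libraries were set beside 20 simulations of unchanged groups. In these all libraries, PBS included, were drawn around the PBS means. Principal components and correlations were computed on log2 CPM with a prior count of 2. A retention step chose genes by their ATEV change and measured them for each EV in other libraries (mean log2 CPM of at least 2). The statistical steps were tested on simulated data drawn from the real means and library sizes for ATEV against PBS with 200 of 15197 genes changed, 100 at each fold size. There edgeR called 25% of genes changed 2-fold and 96% of those changed 4-fold, 3.97% of the calls were unchanged genes, and 0 genes were called when no gene was changed. The retention step measured 28.2% where 30% had been simulated, with its choice limited to the 200 changed genes and libraries drawn independently. That does not test the step over all genes or with libraries that vary together. The rates of calls also came from libraries drawn independently, whereas deviations of same-numbered EV libraries correlated at 0.485 to 0.552. These rates were not split by expression level. Of the 788 genes called for ATEV against PBS, 326 had a mean log2 CPM under the minimum for named genes. The simulated rates may therefore not hold for the real libraries.

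Alternatives fixed in advance were DESeq2 1.42.0, DESeq2's size factors within edgeR, no count filter, a stricter filter of at least 1 CPM in at least 2 libraries, a fit of the libraries of the 2 groups only, the replicate number as a block, and leaving out each library in turn. Protein-coding genes only, a correction for transcript GC content by a lowess curve per library, a fit without the PBS libraries, and the comparison of DNase-treated ATEV with NTEV were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.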

Results

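RNA was sequenced from a clonal line of mouse pancreatic cancer cells of low immunogenicity. The line came from genetically engineered mice that carry a YFP reporter. Cells in culture received PBS, ATEVs, NTEVs or ATEVs pretreated with a DNase. NTEVs are extracellular vesicles (EVs, membrane-bound particles released by cells) of non-activated T cells, and ATEVs are taken here, by contrast with that name, to be EVs of activated T cells. ATEVs were given at 15 µg/mL with or without DNase pretreatment, and NTEVs at 30 µg/mL, amounts read here as each corresponding to 5 µg/mL of EV-DNA before any pretreatment. After each exposure the cells were harvested and reseeded the next day, and the cycle was repeated 8 times. Each of the 4 groups had 2 libraries. Total gene counts were 52451398 and 34385326 with PBS, 44104540 and 43330950 with ATEVs, 51749114 and 40115262 with NTEVs, and 40345707 and 38260045 with DNase-treated ATEVs. Of 42687 genes, 25199 had a count in some library and 15197 were tested. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below 0.333, so all p-values come from models that share the spread over groups and genes.

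The PBS libraries lay apart from all EV-treated libraries. Principal component 1 held 43.2% of the variance, with the PBS libraries at -63.3 and -73.4 and the 6 other libraries between -14.8 and 62.6. Principal component 2 held 24.8% and placed the ATEV libraries at 68.5 and 21.5, the NTEV libraries at -14.3 and -43.7, and the DNase-treated ATEV libraries at -9.84 and -40.6. Pearson's r of log2 counts-per-million across genes was 0.990 between the PBS libraries, 0.980 between the ATEV libraries, 0.985 between the NTEV libraries and 0.983 between the DNase-treated ATEV libraries. It ran from 0.942 to 0.979 between PBS and EV-treated libraries, and from 0.957 to 0.985 between libraries of different EV groups. The highest of the latter were same-numbered NTEV and DNase-treated ATEV libraries (0.985 and 0.983). Replicates of a group thus did not always correlate more highly than libraries of different groups. For libraries that vary independently, chance separates both of a group from both of another for 33.3% of genes. The observed shares against PBS were 52.5% with ATEVs, 59.5% with NTEVs and 60.6% with DNase-treated ATEVs. Between ATEVs and NTEVs the share was 30.0%, and between DNase-treated and untreated ATEVs 36.2%, but deviations of same-numbered libraries of the EV groups correlated at 0.485 to 0.552, so the chance value does not hold for these shares.

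**Figure D1:**
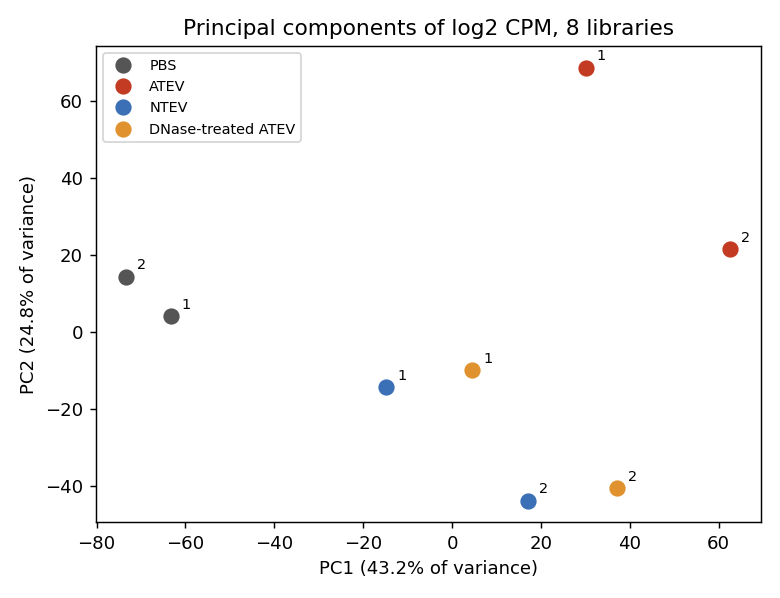
Principal components 1 (43.2% of the variance) and 2 (24.8%) of log2 counts-per-million over the tested genes, with a point per library and a colour per group. The PBS libraries sit at -63.3 and -73.4 on the horizontal axis, and the EV-treated libraries between -14.8 and 62.6.

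Repeated exposure to ATEVs raised the genes of antigen presentation far above their levels with PBS, the comparison that asks what EVs of activated T cells did to the cells. H2-K1, a class I heavy chain, was at 2288 ± 408 counts-per-million (CPM, mean ± SD, n = 2) against 193 ± 3.59 with PBS, an 11.9-fold difference. H2-D1, another heavy chain, rose 7.82-fold to 2086 ± 292 CPM and B2m, the light chain of class I molecules, rose 8.38-fold to 1734 ± 303 CPM. Tap1, a subunit of the transporter that loads peptides into the endoplasmic reticulum, went from 0.877 ± 0.381 to 295 ± 74.5 CPM. Psmb8 and Psmb9, subunits of the immunoproteasome, reached 255 ± 85.7 and 113 ± 33.3 CPM from 0.0942 ± 0.00421 and 0.245 ± 0.175 CPM. Nlrc5, the transactivator of class I genes, reached 129.9 ± 29.9 CPM from 0.185 ± 0.125. By edgeR's quasi-likelihood test, the adjusted p was 0.000622 for H2-K1, H2-D1 and Tap1, 0.00232 for B2m, 8.31e-05 for Psmb8, 0.000608 for Psmb9 and 0.00231 for Nlrc5. Of 25 tested members of the class I list 19 rose, and 21 when adjusted over the list alone. The list stood apart from other genes (median log2 fold change 2.49, camera adjusted p = 8.77e-66), with adjusted p = 0.0190 with an estimated correlation. Members of the H2-K, H2-D, H2-Q and H2-T families resemble each other, so the split of reads between them is uncertain. Without PBS library 1, or without PBS library 2, 12 members passed.

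Genes of the class II pathway, which presents peptides to helper T cells, also rose with ATEVs. Cd74, the invariant chain, was at 442 ± 57.8 CPM against 0.0401 ± 0.0292 with PBS, a ratio of 12429.7 with a 95% counting interval of 4253 to 60276. H2-Aa, a class II alpha chain, was at 96.4 ± 21.1 CPM with no count in the PBS libraries, at least 2710-fold higher when PBS is set to the floor of 3 counts over the group. H2-DMb1 and H2-DMa, which help load class II molecules, reached 58.3 ± 18.3 and 37.9 ± 14.7 CPM, log2 fold changes of 8.08 and 6.04. Of 11 tested members 7 rose, and 8 when adjusted over the list alone, with a median of 8.08, camera adjusted p = 2.20e-58 and adjusted p = 0.0190 with an estimated correlation.

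**Figure D2:**
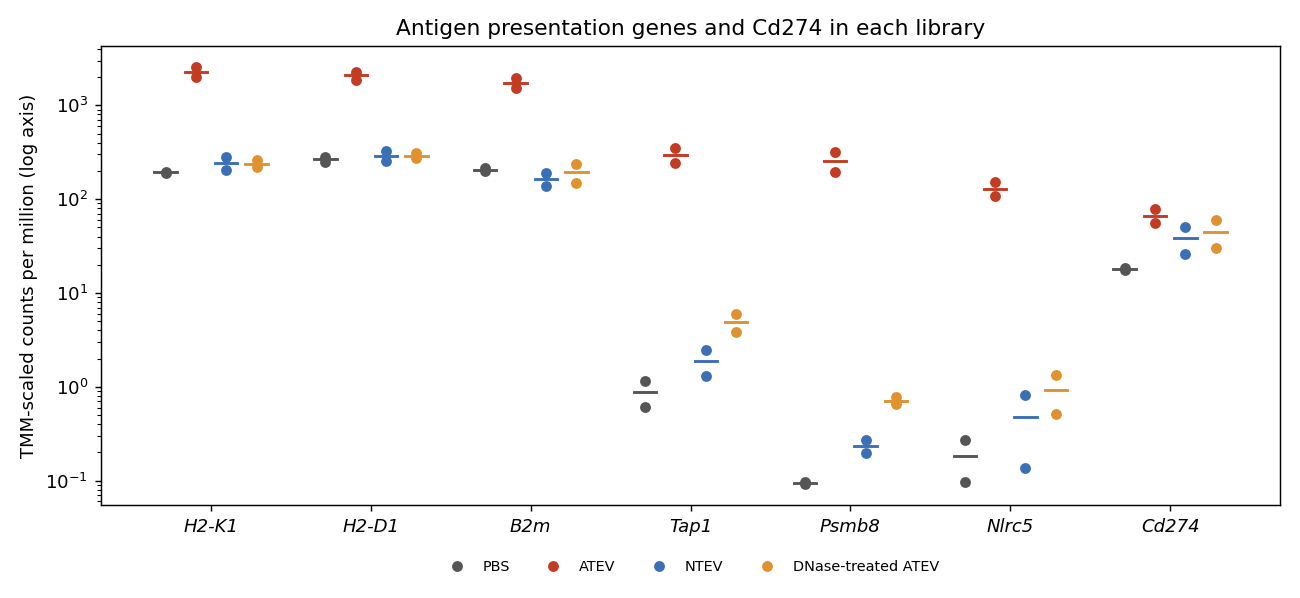
TMM-scaled counts-per-million on a log axis for 7 genes of class I presentation and checkpoint ligands in the 4 groups, with a point per library and a dash at the group mean. H2-K1 has a mean of 2288 with ATEVs, and 193, 242 and 240.0 with PBS, NTEVs and DNase-treated ATEVs.

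Interferon-stimulated genes formed the other large group that rose with ATEVs. Zbp1, a sensor of nucleic acids in the Z form, was at 40.9 ± 14.0 CPM against 0.0692 ± 0.0120 with PBS. Oasl2, a relative of the oligoadenylate synthetases, was at 100.2 ± 0.0616 CPM against 2.06 ± 0.331. Parp14, an ADP-ribosyltransferase, and Dtx3l, a ubiquitin ligase, rose by log2 3.93 and 2.20. Among genes induced by interferon gamma, Casp1, an inflammatory caspase, was at 16.3 ± 0.0584 against 0.148 ± 0.0377 CPM, and Iigp1, an immunity-related GTPase, at 823 ± 408 against 0.0291 ± 0.0412 CPM. Tgtp2, of the same family, was at 130.2 ± 71.9 CPM, a ratio of 5485 with a 95% counting interval of 1518 to 45296. The guanylate-binding proteins Gbp3 and Gbp4 rose by log2 8.80 and 8.82, and Gbp2 was at 828 ± 789 CPM against 1.68 ± 0.155. Of 50 tested members of the type I interferon-stimulated list 40 rose, and 49 when adjusted over the list alone (median log2 fold change 3.25, camera adjusted p = 7.98e-76, adjusted p = 0.0562 with an estimated correlation). Of 32 interferon gamma-induced members 30 rose, and 32 when adjusted over the list alone (median 6.65, camera adjusted p = 3.44e-77, adjusted p = 0.0562 with an estimated correlation). Their median was 5.97 with genes at 0 counts in a group set to their bound. Without PBS library 1 the 2 lists had 13 and 12 members called, and without PBS library 2 they had 11 and 9. Gbp2 lost its call without either PBS library (highest edgeR adjusted p = 0.0814). Reads of the Gbp and immunity-related GTPase families may be split uncertainly between near-identical members.

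Smaller groups also changed with ATEVs. Among sensors of cytosolic nucleic acids 6 of 22 rose, and 8 when adjusted over the list alone, among them Ifi203 (log2 4.20) and the RNA sensors Ddx58 (1.92) and Ifih1 (1.73). Their camera adjusted p was 1.66e-07, with adjusted p = 0.0562 with an estimated correlation. Of 34 NF-kB targets, cytokines and chemokines 8 rose, and 10 rose and 2 fell when adjusted over the list alone. They included Csf1, a macrophage growth factor (190.3 ± 17.8 against 54.4 ± 0.625 CPM), and Nfkbiz, a nuclear regulator of NF-kB (125 ± 33.7 against 45.8 ± 2.80 CPM). That list had a median of 0.81, camera adjusted p = 3.32e-07 and adjusted p = 0.241 with an estimated correlation. Of 21 mesenchymal genes 5 rose, and 10 when adjusted over the list alone, among them Fstl1, a secreted glycoprotein (26.4 ± 3.59 against 2.04 ± 0.304 CPM), and Acta2, smooth muscle actin (39.2 ± 0.907 against 5.58 CPM). Its median was 0.50, with camera adjusted p = 6.08e-05 and adjusted p = 0.0730 with an estimated correlation. Of 9 markers of fibroblasts and endothelium, cells other than the cultured line, 7 were higher and 2 rose, both also when adjusted over the list alone: Acta2, which is in both lists, and Pdpn, which encodes podoplanin and was chosen after its values were seen (log2 2.41, edgeR adjusted p = 0.0496). Their median was 0.35, with camera adjusted p = 0.0945 and a mixed fry adjusted p of 0.00395. Without ATEV library 1 the camera adjusted p was 0.00980, and without ATEV library 2 the median turned to -0.23 (camera adjusted p = 0.560). Of 18 checkpoint and costimulatory ligands 4 rose, and 4 rose and 1 fell when adjusted over the list alone: Tnfrsf14, Icam1, an adhesion molecule, Cd47, which inhibits phagocytosis, and Cd274, which encodes PD-L1. Cd274 was at 66.8 ± 15.8 against 18.1 ± 0.604 CPM (edgeR adjusted p = 0.0491). The ligand list as a whole had a median of 0.04 and a camera adjusted p of 0.180. Calls in these lists depended most on the PBS libraries. Without PBS library 1 the counts were 3 for nucleic acid sensors, 1 for mesenchymal genes and 0 for NF-kB genes, the last with 11 higher and 3 lower at an unadjusted p under 0.05, and without PBS library 2 each was 1. Without ATEV library 1 the mesenchymal and NF-kB counts were 3 and 6, and without ATEV library 2 they were 3 and 5. The Pdpn call was lost in all 4 leave-one-out fits (highest edgeR adjusted p 0.276). All 4 ligands and the Csf1, Nfkbiz and Acta2 calls were lost without either PBS library (highest edgeR adjusted p 0.146, 0.133 and 0.105 for these 3 genes), that of Csf1 also without ATEV library 2, and Cd274 and Cd47 also without either ATEV library (highest edgeR adjusted p 0.271 and 0.195).

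Epithelial and matrix genes went both ways with ATEVs. Ehf, an epithelial transcription factor, rose to 44.7 ± 6.13 CPM from 3.93 ± 0.654 (edgeR adjusted p = 0.000859), while St14, a membrane protease, fell by 3.17 on the log2 scale. These were the 2 calls among 35 epithelial and pancreatic ductal genes, where 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.943). Among 27 matrix genes Col5a1, a fibrillar collagen chain, rose by log2 2.34, and 3 genes fell, among them Col6a2, a collagen chain, and Plau, the urokinase activator (3 rose and 5 fell when adjusted over the list alone). The matrix list had a median of 0.09 and a mean of 0.27, while camera placed it below other genes (adjusted p = 0.715). Further falls included Homer2, a scaffold protein (9.92 ± 0.636 against 57.0 ± 1.05 CPM), Serpinb5, a serpin known as maspin (5.61 ± 0.613 against 28 ± 0.555 CPM), and Slc4a11, a membrane transporter (1.65 ± 0.607 against 9.89 ± 1.23 CPM). Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 939.7 ± 85.7 to 173 ± 19.4 CPM (edgeR adjusted p = 0.000836). Reads of ribosomal RNA may be counted at Lars2, and Gm15564, a ribosomal RNA-like locus chosen after its values were seen, fell as well, by log2 2.95 with ATEVs, 3.05 with NTEVs and 3.14 with DNase-treated ATEVs against PBS. The other such loci tested did not follow. In the same order Gm26917 changed by log2 1.16, 1.21 and 1.10 and Gm42418 by -0.18, -0.09 and -0.35, and neither passed edgeR. Col6a2 and Plau lost their calls in all 4 leave-one-out fits, St14 without either PBS library or ATEV library 1, and Col5a1 without PBS library 2 (highest edgeR adjusted p 0.133, 0.269, 0.228 and 0.0537).

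In all, edgeR called 535 genes higher and 253 lower with ATEVs than with PBS, and 3326 at an unadjusted p under 0.05. Pseudogenes made up 110 of the higher and 105 of the lower genes, and 462 and 188 genes differed at least 2-fold. DESeq2 called 1471, and a fit of protein-coding genes alone, chosen after the data were seen, called 370. The count was 142 without PBS library 1, 131 without PBS library 2, 401 without ATEV library 1 and 346 without ATEV library 2. Over protein-coding genes the log2 fold change rose with the GC content of the transcript (Spearman's rho 0.378 across genes, which are not independent replicates).

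With NTEVs, the control for exposure to T cell EVs as such, the antigen presentation genes named here did not pass against PBS. H2-K1 was at 242 ± 54.3 CPM against 193 ± 3.59 (log2 fold change 0.32 ± 0.20 SE, edgeR adjusted p = 0.385) and H2-D1 at 291 ± 46.3 against 267 ± 23.1 CPM (adjusted p = 0.679). B2m was at 165 ± 37.2 against 207 ± 12.4 CPM, Tap1 at 1.90 ± 0.834 against 0.877 ± 0.381 (2.07-fold), Psmb8 at 0.235 ± 0.0554 against 0.0942 ± 0.00421 (2.40-fold), Nlrc5 at 0.479 ± 0.484 against 0.185 ± 0.125 (2.65-fold) and Cd274 at 38.2 ± 17.2 against 18.1 ± 0.604 CPM (2.11-fold), with edgeR adjusted p of 0.478, 0.262, 0.264, 0.430 and 0.227. Of 25 class I members 0 passed edgeR, with 1 higher and 3 lower at an unadjusted p under 0.05 and 0 by DESeq2, and of 11 class II members 0 passed edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Among 50 type I interferon-stimulated genes 0 passed edgeR, with 19 higher at an unadjusted p under 0.05, 10 by DESeq2 and 2 adjusted over the list alone. That list lay above other genes (median 0.53, camera adjusted p = 1.52e-05, adjusted p = 0.831 with an estimated correlation). Of 32 interferon gamma-induced genes 0 passed edgeR, with 4 higher at an unadjusted p under 0.05 and 2 by DESeq2 (median 0.66, or 0.64 with bounded values; camera adjusted p = 0.0104, adjusted p = 0.831 with an estimated correlation). For class I and class II the camera adjusted p was 0.613 and 0.741. The gamma-induced list lost its camera call without PBS library 2 (adjusted p = 0.0603) and without NTEV library 2 (adjusted p = 0.236).

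The genes that passed with NTEVs were few and of mixed kinds. Hspg2, the basement membrane proteoglycan perlecan, was at 928 ± 157 CPM against 355 ± 5.26 with PBS, and Notch1, a receptor of cell-to-cell signalling, at 132 ± 25.3 against 56.4 ± 9.73. Syne2, which links the nucleus to the cytoskeleton, was at 135 ± 7.93 against 57.0 ± 4.01 CPM and Pkhd1l1, a membrane protein, at 364 ± 80.1 against 115 ± 4.83 CPM. Lars2 fell from 939.7 ± 85.7 to 189 ± 25.2 CPM, Lypla1, a thioesterase, from 82.4 ± 4.22 to 28.7 ± 4.63, Cav2, a caveolin, from 337 ± 44.4 to 155 ± 26.2, and Rps29, a ribosomal protein, from 286 ± 13.1 to 153 ± 6.6 CPM. Their edgeR adjusted p ran from 0.00368 for Lars2 to 0.0349 for Pkhd1l1 among the genes given with values, Rps29 apart. Of the nucleic acid sensing, ligand, NF-kB, mesenchymal, epithelial and matrix lists 0 members passed edgeR. Their counts higher and lower at an unadjusted p under 0.05 were 5 and 1, 3 and 0, 3 and 0, 1 and 3, 5 and 1, and 3 and 2, and DESeq2 called 0, 1, 1, 0, 1 and 2. Adjusted over the list alone, 1 epithelial and 1 matrix member passed. The epithelial list had a median of 0.24 (camera adjusted p = 0.0474, adjusted p = 0.831 with an estimated correlation), and the camera adjusted p of the other lists was 0.741, 0.288, 0.142, 0.613 and 0.0616. Without PBS library 2 the epithelial list had a camera adjusted p of 0.0603, and without NTEV library 2 0.233.

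In all, 107 genes were higher and 62 lower with NTEVs by edgeR, 2907 at an unadjusted p under 0.05 and 768 by DESeq2. Pseudogenes made up 55 of the higher and 49 of the lower genes, and the fit of protein-coding genes alone called 1, Lars2. The total was 11 without PBS library 1, 5 without PBS library 2, 25 without NTEV library 1 and 28 without NTEV library 2. Of the 20 genes named by the rule 17 lost their call in all 4 of these fits and 0 kept it in all 4, with Lars2 lost without PBS library 2 alone (edgeR adjusted p = 0.0511). Spearman's rho of the fold change with GC content was 0.387.

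DNase-treated ATEVs, the group that addresses the EV-DNA, differed from PBS in interferon-stimulated and NF-kB genes. Lcn2, an iron-sequestering acute phase protein, was at 51.0 ± 15.1 CPM against 0.0291 with PBS, a ratio of 1439.6 with a 95% counting interval of 492 to 6984. Nfkbiz rose to 233 ± 28.4 CPM from 45.8 ± 2.80, Csf1 to 267 ± 119 from 54.4 ± 0.625, and Nos2, the inducible nitric oxide synthase, was at 6.86 ± 5.26 CPM (a ratio of 291, interval 80.3 to 2413). Of 34 NF-kB targets, cytokines and chemokines 12 rose, and 16 when adjusted over the list alone (median 0.91, camera adjusted p = 1.72e-17, adjusted p = 0.378 with an estimated correlation). Of 50 type I interferon-stimulated genes 17 rose, and 40 when adjusted over the list alone (median 2.11, or 1.92 with bounded values; camera adjusted p = 6.57e-27, adjusted p = 0.736 with an estimated correlation). They included Oasl2 (30.0 ± 10.7 against 2.06 ± 0.331 CPM), Mx2, an antiviral GTPase (11.6 ± 4.85 against 0.565 CPM), Ifit1, which binds viral RNA (7.77 ± 1.20 against 0.370 CPM), and Rtp4 (22.6 ± 10.3 CPM). Of 32 interferon gamma-induced genes 4 rose, and 11 when adjusted over the list alone, among them Gbp3 (8.17 ± 2.07 against 0.467 CPM), Casp1 (log2 2.55) and Fas, a death receptor (log2 3.28). Its median was 1.43, or 1.39 with bounded values (camera adjusted p = 2.00e-08, adjusted p = 0.821 with an estimated correlation). Without PBS library 1 all of these NF-kB and interferon calls were lost, and without PBS library 2 all but 1 NF-kB call. Without DNase-treated library 1 the NF-kB, type I and interferon gamma counts were 5, 5 and 0, and without library 2 they were 7, 3 and 0, with 15 and 9 gamma members higher at an unadjusted p under 0.05 by edgeR. In the fit of protein-coding genes alone 5 NF-kB and 2 type I members passed.

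With DNase-treated ATEVs H2-K1, H2-D1 and B2m did not pass against PBS, while Tap1 and Psmb8 rose. H2-K1 was at 240.0 ± 28.4 CPM (log2 fold change 0.31, edgeR adjusted p = 0.359), H2-D1 at 292 ± 24.0 (adjusted p = 0.656) and B2m at 193 ± 62.4 (adjusted p = 0.837). Tap1 rose to 4.90 ± 1.55 CPM from 0.877 ± 0.381 (edgeR adjusted p = 0.0380) and Psmb8 to 0.713 ± 0.0835 from 0.0942 ± 0.00421 (adjusted p = 0.0284). These were the 2 calls among 25 class I members, where 4 rose and 2 fell when adjusted over the list alone (median 0.42, camera adjusted p = 0.0441, adjusted p = 0.821 with an estimated correlation), and both were lost in each of the 4 fits that left out a PBS or DNase-treated library (highest edgeR adjusted p 0.241 and 0.203). The camera call of the list ended without PBS library 1, PBS library 2 or DNase-treated library 2 (adjusted p 0.126, 0.0611 and 0.146). Of 11 class II members 0 passed edgeR, with 2 higher and 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (camera adjusted p = 0.948). Nlrc5 was at 0.926 ± 0.591 (5.36-fold PBS) and Cd274 at 45.2 ± 21.7 CPM (edgeR adjusted p 0.165 and 0.118).

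Named genes outside class I changed as well with DNase-treated ATEVs. C3, the central complement component, was at 222 ± 70.3 CPM against 2.68 ± 0.993 with PBS, and Pou2f2, a transcription factor, at 29.1 ± 1.32 against 0.621 ± 0.276. Ltbp2, a matrix protein, rose to 57.1 ± 3.81 from 1.66 ± 0.119 CPM (edgeR adjusted p = 0.000301). Cybb, a subunit of the phagocyte NADPH oxidase, was at 24.3 ± 7.14 against 0.918 CPM, and Ehf at 34.4 ± 6.93 against 3.93 ± 0.654 CPM. Ehf and Tjp3, a tight junction protein (log2 1.27), were the 2 that rose of 35 epithelial genes, with 2 adjusted over the list alone (camera adjusted p = 0.576). Among 27 matrix genes Col5a1 and Lama5 rose and 2 fell, among them Timp3 (2 rose and 3 fell when adjusted over the list alone, camera adjusted p = 0.875). Of 22 nucleic acid sensors 4 rose, and 7 when adjusted over the list alone, namely Ifi203, Zbp1, Adar and Ddx58 over all genes (camera adjusted p = 0.0441, adjusted p = 0.821 with an estimated correlation). Among 18 ligands Cd47 rose and H60b fell (2 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.656). Of 21 mesenchymal genes 0 passed edgeR, with 3 higher and 2 lower at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.931). Lars2 fell from 939.7 ± 85.7 to 157 ± 0.574 CPM (edgeR adjusted p = 0.00170). Of 41 genes named for this comparison, Ltbp2 and Lars2 kept their call in all 4 leave-one-out fits. The others lost it without at least 1 library, among them C3 in all 4 fits (highest edgeR adjusted p = 0.248) and Pou2f2 and Ehf without PBS library 2 (0.0607 each). The camera call of the nucleic acid sensors ended without PBS library 2, DNase-treated library 1 or DNase-treated library 2 (adjusted p 0.118, 0.0724 and 0.104).

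In all, 328 genes were higher and 130 lower than with PBS by edgeR, 3749 at an unadjusted p under 0.05 and 1513 by DESeq2. Pseudogenes made up 79 of the higher and 64 of the lower genes, and the fit of protein-coding genes alone called 33. The total was 20 without PBS library 1, 11 without PBS library 2, 68 without DNase-treated library 1 and 57 without library 2. Spearman's rho of the fold change with GC content was 0.307.

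ATEVs and NTEVs were compared directly to ask what the activation state of the T cells added at matched EV-DNA, with the NTEV amount being larger. Class I genes were higher with ATEVs, H2-K1 by 9.47-fold, H2-D1 by 7.17-fold, B2m by 10.5-fold and Tap1 by 157-fold, with edgeR adjusted p of 0.00128, 0.00117, 0.00289 and 0.00122. Psmb8 was higher by log2 10.09 (adjusted p = 0.000101) and Nlrc5 by 8.15. Of 25 class I members 16 were higher, and 21 when adjusted over the list alone (median 2.60, camera adjusted p = 1.76e-127, adjusted p = 0.00366 with an estimated correlation). Of 11 class II members 7 were higher, and 7 when adjusted over the list alone, among them Cd74, at 0.032 ± 0.01 CPM with NTEVs, a ratio of 13455 with a 95% counting interval of 4604 to 65246, and H2-Aa, at least 2934-fold higher. Their median was 7.81, with camera adjusted p = 2.43e-118 and adjusted p = 0.00366 with an estimated correlation. Cd274 differed by log2 0.81 ± 0.40 SE, which did not pass (edgeR adjusted p = 0.747).

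Interferon-induced genes were likewise higher with ATEVs than with NTEVs. Casp1 differed by log2 5.75, Iigp1 by 12.17, Gbp3 by 7.01 (207 ± 132 against 1.61 ± 0.290 CPM) and Oasl2 by 3.49 (100.2 ± 0.0616 against 8.92 ± 3.65 CPM). Of 32 interferon gamma-induced genes 24 were higher, and 32 when adjusted over the list alone (median 5.76, or 5.74 with bounded values; camera adjusted p = 7.72e-132, adjusted p = 0.0204 with an estimated correlation). Of 50 type I interferon-stimulated genes 25 were higher, and 44 when adjusted over the list alone (median 2.30, camera adjusted p = 1.48e-103, adjusted p = 0.0204 with an estimated correlation). Zbp1, with a ratio of 1244 (95% counting interval 425 to 6036), and Ifi203 were the 2 higher of 22 nucleic acid sensors, with 9 adjusted over the list alone (camera adjusted p = 1.08e-12, adjusted p = 0.0204 with an estimated correlation). Without NTEV library 1 the interferon gamma and type I counts were 12 and 8, and without NTEV library 2 they were 14 and 15. Without the PBS libraries, an alternative chosen after the data were seen, the type I count was 14. Among the sensors, Ifi203 lost its call without either ATEV library and without NTEV library 1 (log2 2.49 to 3.56 over the 4 leave-one-out fits).

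Other lists also differed between ATEVs and NTEVs. Of 21 mesenchymal genes 5 were higher with ATEVs, and 7 when adjusted over the list alone, among them Fstl1 (log2 3.96), Acta2 (39.2 ± 0.907 against 3.05 ± 1.77 CPM), Fbn1, a microfibril protein (log2 5.78), and Prrx1, a mesenchymal transcription factor (log2 2.52). Their median was 0.27 (camera adjusted p = 2.44e-10, adjusted p = 0.0204 with an estimated correlation). Of the 9 fibroblast and endothelial markers Acta2 was the 1 called higher, with 2 adjusted over the list alone (median 0.04, camera adjusted p = 0.0594, mixed fry adjusted p = 0.000606). That camera p was 7.77e-05, 0.0116 and 0.00627 without ATEV library 1, NTEV library 1 and NTEV library 2, and without ATEV library 2 the median turned to -0.22 (camera adjusted p = 0.757). Nos2, Lcn2 and the chemokines Ccl2 (24.9 ± 0.717 against 1.67 ± 0.181 CPM) and Cxcl3 were the 4 higher of 34 NF-kB members, with 8 adjusted over the list alone (median 0.39, camera adjusted p = 2.01e-07, adjusted p = 0.211 with an estimated correlation). Tnfrsf14 and Icam1 were the 2 higher of 18 ligands, with 3 adjusted over the list alone (camera adjusted p = 0.551). Ehf was higher by log2 3.19, the 1 call over all genes among 35 epithelial members (1 higher and 1 lower when adjusted over the list alone), while the list lay below other genes (median -0.26, camera adjusted p = 0.0180, adjusted p = 0.650 with an estimated correlation). Of 27 matrix genes 1 was lower (2 higher and 4 lower when adjusted over the list alone; median -0.40, camera adjusted p = 0.00353, adjusted p = 0.640 with an estimated correlation). Homer2 (9.92 ± 0.636 against 62.6 ± 4.05 CPM) and Onecut3, a transcription factor (6.65 ± 0.726 against 21.2 ± 0.852 CPM), were lower with ATEVs, as was Muc5ac, a gastric mucin (0.297 ± 0.258 against 21.7 ± 16 CPM, edgeR adjusted p = 0.0462). Muc5ac and Ccl2 lost their calls in all 4 leave-one-out fits (highest edgeR adjusted p 0.217 and 0.215), as did the matrix call. Without NTEV library 1 the calls of Nos2, Lcn2, Cxcl3, Tnfrsf14, Icam1, Prrx1 and Fbn1 were lost, without ATEV library 1 those of Cxcl3, Tnfrsf14, Icam1, Prrx1 and Fbn1, and without NTEV library 2 those of Lcn2, Cxcl3, Icam1 and Fbn1 (highest edgeR adjusted p 0.0732, 0.140, 0.290, 0.140, 0.272, 0.105 and 0.104 in the order of the first list). The mesenchymal count was 2 without ATEV library 1 or NTEV library 1, 4 without ATEV library 2 and 3 without NTEV library 2. Without ATEV library 1 or NTEV library 2 the camera calls of the epithelial list (adjusted p 0.497 and 0.142) and of the matrix list (adjusted p 0.594 and 0.151) ended.

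In all, 159 genes were higher and 22 lower with ATEVs than with NTEVs by edgeR, and 1251 had an unadjusted p under 0.05. DESeq2 called 469, 332 higher and 137 lower. A fit of the libraries of the 2 groups only called 50 higher and 1 lower. Pseudogenes made up 5 of the higher genes and 1 of the lower, and rho with GC content was -0.0356. The total was 110 without the PBS libraries, 115 without ATEV library 1, 71 without NTEV library 1 and 94 without NTEV library 2.

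DNase pretreatment of ATEVs was compared with untreated ATEVs to ask how far the changes rested on DNA that the enzyme can reach. H2-K1 was at 240.0 ± 28.4 CPM with DNase-treated ATEVs against 2288 ± 408 with untreated ATEVs, a log2 fold change of -3.25 (edgeR adjusted p = 0.00180). H2-D1 was at 292 ± 24.0 against 2086 ± 292 CPM (adjusted p = 0.00180), B2m at 193 ± 62.4 against 1734 ± 303 (adjusted p = 0.00556), and Tap1 at 4.90 ± 1.55 against 295 ± 74.5 CPM (adjusted p = 0.00294). Psmb8 was at 0.713 ± 0.0835 against 255 ± 85.7 CPM and Nlrc5 at 0.926 ± 0.591 against 129.9 ± 29.9 CPM. Of 25 class I members 14 fell, and 19 when adjusted over the list alone (median -2.08, camera adjusted p = 5.13e-113, adjusted p = 0.00512 with an estimated correlation). Of 11 class II members 7 fell, and 7 when adjusted over the list alone (median -7.67, camera adjusted p = 8.44e-114, adjusted p = 0.00512 with an estimated correlation). Among them Cd74 went from 442 ± 57.8 to 0.0868 ± 0.0885 CPM (log2 -12.28, edgeR adjusted p = 0.000172). H2-K1, H2-D1, B2m, Tap1, Psmb8 and Cd74 kept their call without any of the 4 libraries in turn, and Nlrc5 lost it without either DNase-treated library (highest edgeR adjusted p = 0.0999).

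Interferon-induced genes fell too, the gamma-induced list in more of its members than the type I list. Iigp1 changed by log2 -10.66, Tgtp2 by -8.61, Casp1 by -4.16 (0.907 ± 0.121 against 16.3 ± 0.0584 CPM) and Gbp3 by -4.67. Of 32 interferon gamma-induced genes 20 fell, and 32 when adjusted over the list alone (median -4.69, camera adjusted p = 3.66e-104, adjusted p = 0.0429 with an estimated correlation). Of 50 type I interferon-stimulated genes 8 fell, and 29 fell and 1 rose when adjusted over the list alone (median -0.997, camera adjusted p = 9.87e-41, adjusted p = 0.0976 with an estimated correlation). The difference between the lists was not itself tested. The 8 included Cmpk2, a mitochondrial nucleotide kinase (log2 -5.47), and Zbp1 (0.835 ± 0.0860 against 40.9 ± 14.0 CPM). Zbp1 was also the 1 call among 22 nucleic acid sensors, with 6 adjusted over the list alone (camera adjusted p = 5.89e-07, adjusted p = 0.0779 with an estimated correlation). The gamma-induced and type I counts were 12 and 3 without ATEV library 1, 3 and 1 without DNase-treated library 1, 5 and 2 without DNase-treated library 2, and 8 and 5 without the PBS libraries. Gbp3 lost its call without either DNase-treated library (highest edgeR adjusted p = 0.122), and Zbp1 without library 1 (0.0600).

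NF-kB genes did not follow the antigen presentation genes after DNase pretreatment. Lcn2 was at 51.0 ± 15.1 CPM against 5.57 ± 4.13 with untreated ATEVs (log2 3.20, edgeR adjusted p = 0.0797) and Cxcl1, a neutrophil chemokine, at 191 ± 92.6 against 31.9 ± 1.19 CPM (log2 2.58, adjusted p = 0.176). Of 34 members 0 passed edgeR over all genes, with 12 higher at an unadjusted p under 0.05, 6 by DESeq2 and 7 adjusted over the list alone. The list lay above other genes by camera (median 0.38, adjusted p = 1.93e-06, adjusted p = 0.278 with an estimated correlation), and fry gave an adjusted p of 0.132. Of 21 mesenchymal genes 3 fell, and 5 when adjusted over the list alone, namely Fstl1 (1.26 ± 0.0270 against 26.4 ± 3.59 CPM), Acta2 (log2 -3.22) and Prrx1 (log2 -2.32) over all genes (median -0.23, camera adjusted p = 8.70e-08, adjusted p = 0.0429 with an estimated correlation). Markers of fibroblasts and endothelium, cells other than the cultured line, fell as a list as well (median -0.54, camera adjusted p = 0.0136, adjusted p = 0.506 with an estimated correlation), but without ATEV library 2 the median turned to 0.31. Of these 9 markers 1 passed edgeR, Acta2, which is in both lists. Col1a1, Cdh5 and Eng lay higher after pretreatment (log2 1.16, 0.31 and 0.06) and did not pass. Among 18 ligands Tnfrsf14 fell to 0.760 ± 0.0891 CPM, with 1 adjusted over the list alone (camera adjusted p = 0.178), while Cd274 differed by log2 -0.56 ± 0.40 SE (edgeR adjusted p = 0.689). Of 35 epithelial genes 0 passed edgeR, with 3 higher and 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.410). Of 27 matrix genes 0 passed edgeR, with 4 higher and 1 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 1 adjusted over the list alone (camera adjusted p = 0.384). Genes that were higher after pretreatment included Homer2 (29.4 ± 6.15 against 9.92 ± 0.636 CPM), Serpinb5 (14.6 ± 1.53 against 5.61 ± 0.613), Ltbp2 (57.1 ± 3.81 against 24.4 ± 3.34) and Xist, the X-inactivation RNA (1849 ± 820 against 426 ± 24.2 CPM, edgeR adjusted p = 0.0342). Of the mesenchymal genes 0 passed edgeR without DNase-treated library 1, with 7 lower at an unadjusted p under 0.05, and 1 passed without library 2, and the highest edgeR adjusted p over the 4 leave-one-out fits was 0.0580 for Fstl1, 0.164 for Acta2, 0.251 for Prrx1 and 0.175 for Tnfrsf14. Serpinb5 lost its call in all 4 of these fits, Homer2 without either ATEV library or DNase-treated library 1, Ltbp2 without ATEV library 1 or either DNase-treated library, and Xist without either ATEV library or DNase-treated library 2 (highest edgeR adjusted p 0.195, 0.0580, 0.207 and 0.201).

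In all, 13 genes were higher and 88 lower with DNase-treated than with untreated ATEVs by edgeR, and 1724 had an unadjusted p under 0.05. DESeq2 called 356, 131 higher and 225 lower. A fit of the libraries of the 2 groups only called 0 higher and 47 lower. Pseudogenes made up 1 of the higher and 5 of the lower genes, and rho with GC content was -0.0358. The total was 53 without the PBS libraries, 55 without ATEV library 1, 27 without DNase-treated library 1 and 41 without library 2. Of the 535 genes higher with ATEVs than with PBS, 156 were also higher with ATEVs than with NTEVs, 85 were lower after DNase pretreatment and 81 met both conditions, against 5.6, 3.1 and 0.0324 for independent lists. Of the 253 lower genes 18 were also lower with ATEVs than with NTEVs, 6 were higher after DNase pretreatment and 5 met both conditions, against 0.366, 0.216 and 0.000313. These 5 were Homer2, Onecut3, Serpinb5, Slc4a11 and the pseudogene Tpt1-ps3. Each lost its call after DNase pretreatment without ATEV library 1, and all but Tpt1-ps3 also without DNase-treated library 1 (highest edgeR adjusted p over the leave-one-out fits 0.0580, 0.302, 0.195, 0.203 and 0.0810). Simulated unchanged groups shared 0 such calls for higher genes and a mean of 0.05 in each contrast for lower genes, and gave almost none to share. These comparisons share the ATEV libraries, so part of each overlap may come from them. Of those 535, 223 were also higher with DNase-treated ATEVs than with PBS.

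**Figure D3:**
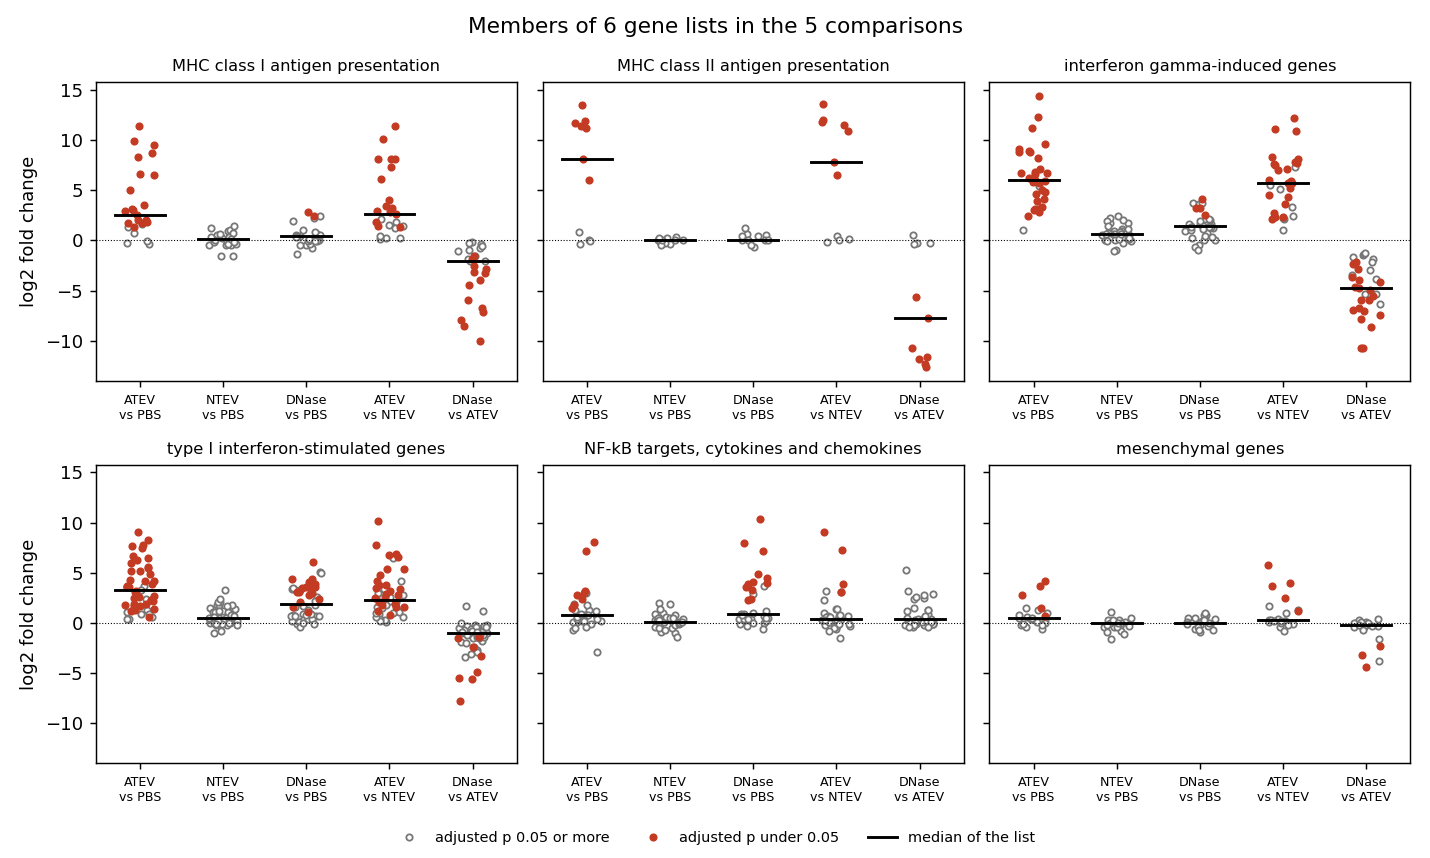
Log2 fold changes of the members of 6 gene lists in the 5 comparisons, with a point per gene, filled where the edgeR adjusted p was under 0.05, and a black bar at the median. Genes with no count in a group are drawn at their bound. The class II median is 8.08 for ATEVs against PBS and -7.67 for DNase-treated against untreated ATEVs, while the NF-kB median is 0.81 and 0.38.

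Some of the remaining lists fixed in advance also shifted, and none of these was called with an estimated correlation. No list test was rerun with the correction for GC content, so the part of GC content in the medians against PBS was not tested. With ATEVs against PBS, hypoxia and glycolysis genes had a median of 0.61 (camera adjusted p = 0.00204, adjusted p = 0.894 with an estimated correlation), MAPK and immediate early genes 0.52 (0.00463 and 0.666) and Myc targets and ribosome biogenesis -0.41 (0.00694 and 0.894). The medians of these 3 lists with NTEVs against PBS were 0.66, 0.67 and -0.54 (camera adjusted p 0.000189, 1.52e-05 and 0.000189). With DNase-treated ATEVs against PBS they were 0.61, 0.84 and -0.51 (camera adjusted p 0.00743, 8.73e-05 and 0.000277). G2 and M phase genes had medians of -0.14, -0.49 and -0.66 in the 3 comparisons with PBS (camera adjusted p 0.214, 0.000192 and 8.73e-05), and S phase genes -0.32, -0.69 and -0.69 (0.0704, 6.74e-05 and 0.000277). For every list called against PBS with NTEVs the adjusted p with an estimated correlation was 0.831, and for those with DNase-treated ATEVs in this paragraph 0.821. With NTEVs oxidative phosphorylation (median -0.21, camera adjusted p = 0.0104) and YAP targets (0.28, adjusted p = 0.0168) were also called. With DNase-treated ATEVs DNA repair (-0.37, adjusted p = 0.0196), cholesterol synthesis (-0.30, adjusted p = 0.0249) and cytosolic heat shock (-0.40, adjusted p = 0.0394) were. ATEVs against NTEVs gave a G2 and M phase median of 0.32 (camera adjusted p = 0.0237, 0.982 as adjusted p with an estimated correlation), ATF4 and amino acid response 0.26 (0.0327 and 0.879) and myeloid and B cell markers 0.35 (0.0311 and 0.211). DNase-treated against untreated ATEVs gave a G2 and M phase median of -0.44 (0.00197 and 0.844), fatty acid synthesis -0.24 (0.0247 and 0.718) and fibroblast and endothelial markers -0.54 (0.0136 and 0.506). The G2 and M phase median turned to -0.146 without ATEV library 1 and -0.0195 without NTEV library 2 in the former comparison, and to 0.0650 without ATEV library 1 in the latter. Of these lists, the 3 called with ATEVs against PBS lost their calls without ATEV library 2 (camera adjusted p 0.334, 0.0809 and 0.596). Those called with NTEVs, MAPK and YAP targets apart, lost theirs without NTEV library 2 (0.0544 to 0.275), and YAP targets without PBS library 1 (0.0549). With DNase-treated ATEVs, S phase, Myc, hypoxia, DNA repair and heat shock lost theirs without DNase-treated library 2 (0.116 to 0.285), and cholesterol synthesis without PBS library 2 (0.879). Without ATEV library 1 the ATF4 and myeloid calls ended in ATEVs against NTEVs (0.413 and 0.0644), and without ATEV library 2 the fatty acid and fibroblast calls ended after DNase pretreatment (0.539 and 0.453), the ATF4 median turning to -0.04 and the fibroblast median to 0.31.

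Lists that were not called with ATEVs against PBS included p53 targets (median 0.02, camera adjusted p = 0.850), DNA repair (-0.13, adjusted p = 0.345), cholesterol synthesis (-0.19, adjusted p = 0.245), fatty acid synthesis (0.09, adjusted p = 0.510) and oxidative phosphorylation (-0.17, adjusted p = 0.0757). The camera adjusted p was 0.452 for the ATF4 and amino acid response, 0.699 for endoplasmic reticulum chaperones, 0.245 for cytosolic heat shock, 0.797 for NRF2 and for Wnt and Notch targets, 0.113 for YAP targets and 0.434 for lysosome and autophagy. Markers of myeloid and B cells and of fibroblasts and endothelium, cells other than the cultured line, had camera adjusted p of 0.219 and 0.0945. By fry the adjusted p was 0.0248 and 0.179, with the myeloid and B cell list higher and its mixed adjusted p at 0.0012. Of its 10 tested members 1 rose, and 2 when adjusted over the list alone. Of 40 T cell markers 4 passed the count filter, under the 5 needed for a test. Their summed level was 23 CPM in each PBS library, 19.4 and 16.6 with ATEVs, 18.4 and 14.3 with NTEVs, and 23.8 and 19.5 with DNase-treated ATEVs.

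The 3 comparisons with PBS shared many calls, and pseudogenes were common among them. ATEVs and NTEVs shared 84 higher and 61 lower genes, of which 103 were pseudogenes, against 3.77 and 1.03 for independent lists. ATEVs and DNase-treated ATEVs shared 223 and 95, of which 134 were pseudogenes, against 11.5 and 2.16. NTEVs and DNase-treated ATEVs shared 84 and 55, of which 98 were pseudogenes, against 2.31 and 0.530. In 20 simulations all libraries, PBS included, were drawn independently around the PBS means. These unchanged groups shared a mean of 0 calls. That sets no level for these overlaps, because such groups gave almost no calls to share. The covariance of the log2 fold changes was 0.464, 0.583 and 0.480 for the 3 pairs, against 0.0826, 0.0830 and 0.0827 simulated, and Pearson's r across genes was 0.655, 0.713 and 0.791, against 0.507, 0.505 and 0.505. The 2 PBS libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. The simulation holds no offset of the actual PBS libraries, since it drew these anew. It also leaves out the correlation of same-numbered EV libraries (0.485 to 0.552). That may raise these values too, which was not tested. In the lowest and the highest of 10 bins of GC content the median log2 fold change was -0.33 and 0.28 with ATEVs, -0.36 and 0.34 with NTEVs, and -0.25 and 0.28 with DNase-treated ATEVs.

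**Figure D4:**
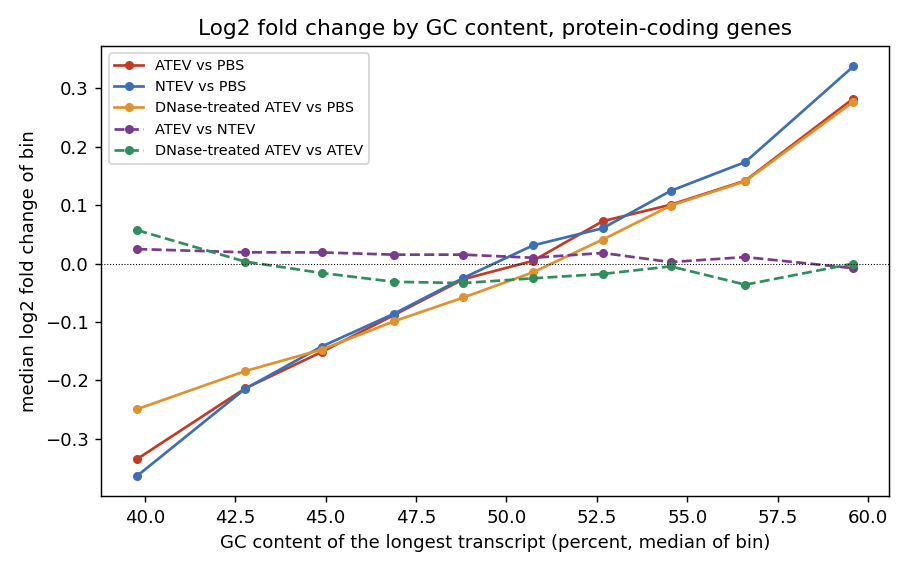
Median log2 fold change of protein-coding genes in 10 bins of transcript GC content, with a line per comparison. The 3 comparisons with PBS run from between -0.36 and -0.25 in the lowest bin to between 0.28 and 0.34 in the highest, and Spearman's rho of the 2 comparisons between EV groups is -0.0356 and -0.0358.

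Genes at least 1 log2 unit apart between ATEVs and PBS were chosen on the libraries of 1 number. Their changes against PBS with each kind of EV were measured in the libraries of the other number. The 262 genes chosen as higher on libraries 1 had a mean log2 change in libraries 2 of 1.93 with ATEVs, 0.76 with NTEVs and 1.30 with DNase-treated ATEVs. The 707 chosen on libraries 2 had 0.75, 0.37 and 0.58 in libraries 1. The 167 genes chosen as lower on libraries 1 had -0.45, 0.28 and -0.02 in libraries 2, and the 592 chosen on libraries 2 had -0.20, -0.21 and -0.27 in libraries 1, so the splits differed in order for lower genes. These are values from a pair of splits with no test.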

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

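The alternatives on protein-coding genes, GC content and the omission of the PBS libraries were chosen only after the results were seen, and the others were planned. Of 275 counts and retained shares recomputed, 132 stayed within their limits and 143 moved. Of 1445 list results 1112 kept direction and side of the threshold, 95 lost the call, 89 gained it, 144 that were not called changed direction and 5 reversed, a list counting as changed in direction when its median or its place by camera changed sign. Of 3795 results for named genes 3125 kept direction and side, 561 lost the call, 100 gained it and 9 moved. With 2 libraries per group the count of calls depended on the test and filter: the numbers of genes called for ATEV vs PBS, NTEV vs PBS, DNase-treated ATEV vs PBS, ATEV vs NTEV and DNase-treated vs untreated ATEV were 1454, 773, 1520, 459 and 343 with no count filter, and 1471, 768, 1513, 469 and 356 with DESeq2. With libraries of the 2 groups only, ATEV vs PBS gave 454, ATEV vs NTEV 51 and DNase-treated vs untreated ATEV 47. Leaving out a library gave 131 to 401, 5 to 28, 11 to 68, 71 to 166 (71 to 115 among those that moved) and 27 to 99 (27 to 55 among those that moved). A library left alone in its group is assumed there to vary like the other groups. Protein-coding genes only gave 370, 1 and 33 for the 3 comparisons with PBS. In the fit of all genes 527, 52 and 258 of the called genes were protein-coding. Leaving pseudogenes and other classes out of the count thus accounts for only part of the drop. GC content correction gave 303 for DNase-treated ATEV vs PBS. Without the PBS libraries ATEV vs NTEV gave 110 and DNase-treated vs untreated ATEV 53, with fewer residual degrees of freedom. Other causes were not tested. DESeq2's calls held 771, 168, 457, 181 and 101 of the 788, 169, 458, 181 and 101 genes called by edgeR.

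With an estimated correlation camera called 2, 0, 0, 6 and 4 lists in the order of comparisons above, so 43 of 55 list calls were lost. The list tests were not rerun with DESeq2, protein-coding genes only, the GC content correction or without the PBS libraries. Leaving out a library gave 7 to 19, 3 to 14, 7 to 14, 10 to 19 and 12 to 16 lists called, against 10, 10, 13, 12 and 10. Leaving out a library gave the G2 and M phase list a median of -0.146 to 0.769 for ATEV vs NTEV and -0.818 to 0.0650 for DNase-treated vs untreated ATEV, the ATF4 and amino acid list a median of -0.0400 to 0.584 for ATEV vs NTEV, and the fibroblast and endothelial markers -1.10 to 0.307 for DNase-treated vs untreated ATEV. The G2 and M phase list reversed for ATEV vs NTEV to -0.146 without ATEV library 1 (camera adjusted p = 0.157) and -0.0195 without NTEV library 2 (adjusted p = 0.624), and for DNase-treated vs untreated ATEV without ATEV library 1 (adjusted p = 0.563). The ATF4 and amino acid list for ATEV vs NTEV reversed without ATEV library 1 (adjusted p = 0.413), and the fibroblast and endothelial markers for DNase-treated vs untreated ATEV without ATEV library 2 (adjusted p = 0.453). The cause was not tested.

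Genes called alike by ATEV and NTEV, by ATEV and DNase-treated ATEV, and by NTEV and DNase-treated ATEV numbered 531, 831 and 550 with no count filter and 523, 804 and 496 with DESeq2. Among genes lower with ATEVs, choosing at 1.5 log2 units gave a mean change over both splits of -0.755 with ATEVs and -0.330 with DNase-treated ATEVs. The splits differed. Genes chosen on libraries 1 had -1.03 with ATEVs, 0.16 with NTEVs and -0.25 with DNase-treated ATEVs. Those chosen on libraries 2 had -0.48, -0.21 and -0.41.

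Of 209 calls of named genes, 66 were lost with libraries of the 2 groups only, 25 with GC content correction and 9 with the stricter filter. Protein-coding genes only lost 44 of 199. All 4 leave-one-out fits kept the calls of 28 of 59 named genes for ATEV vs PBS, 0 of 20 for NTEV vs PBS, 2 of 41 for DNase-treated ATEV vs PBS, 30 of 50 for ATEV vs NTEV and 15 of 39 for DNase-treated vs untreated ATEV.

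No label ties the replicate numbers, although deviations of same-numbered EV libraries correlated. With the replicate block edgeR called 330 genes for NTEV vs PBS and 1052 for DNase-treated ATEV vs PBS, and 267, 596 and 257 genes were called alike by the 3 pairs of comparisons above. Its counts for the other comparisons were 1182, 255 and 127. Deviations of same-numbered libraries correlated at -0.180 for PBS and ATEV, -0.236 for PBS and NTEV, -0.141 for PBS and DNase-treated ATEV, 0.529 for ATEV and NTEV, 0.552 for ATEV and DNase-treated ATEV, and 0.485 for NTEV and DNase-treated ATEV.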

Other observations

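The tests of near-identical copies and of the GC trend were written before their results were seen, and the other tests and the comparison of DNase-treated ATEVs with NTEVs were chosen after. That comparison asks how DNase-treated ATEVs differed from NTEVs. NTEVs were not pretreated and were given at 30 against 15 µg/mL, so activation state, pretreatment and EV amount cannot be told apart in it. The amount of DNA left after pretreatment is not given. Ltbp2, a matrix protein, was at 57.1 ± 3.81 CPM (mean ± SD, n = 2) with DNase-treated ATEVs against 2.35 ± 0.0585 with NTEVs, a log2 fold change of 4.6 (edgeR adjusted p = 0.000495). Pou2f2, a transcription factor, was at 29.1 ± 1.32 against 1.08 ± 0.509 CPM, Clca3b at 56.3 ± 20.6 against 1.44 ± 0.375 CPM, and Ehf, an epithelial transcription factor, at 34.4 ± 6.93 against 4.91 ± 0.416 CPM (edgeR adjusted p 0.0199, 0.0262 and 0.0199). Vnn3, a pantetheinase, was higher by log2 4.46 and Zfpm1, a cofactor of GATA factors, lower by log2 -1.27 (78.9 ± 0.518 against 191 ± 12.2 CPM). In all 7 genes were higher and 1 lower, with 1522 at an unadjusted p under 0.05. Of 34 NF-kB members 1 passed, and 13 when adjusted over the list alone (camera adjusted p = 1.23e-28, adjusted p = 0.144 with an estimated correlation). Of 50 type I interferon-stimulated genes 0 passed edgeR, and 22 when adjusted over the list alone (median 1.28, camera adjusted p = 4.15e-28, adjusted p = 0.439 with an estimated correlation). Of 32 interferon gamma-induced genes 0 passed, and 3 over the list alone (median 0.71, camera adjusted p = 5.75e-07, 0.737 with an estimated correlation). Of 25 class I members 0 passed either way (median 0.05, camera adjusted p = 0.0225, 0.737 with an estimated correlation). Of 11 class II members 0 passed either way (camera adjusted p = 0.577). This comparison was not rerun without single libraries or with another tool.

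The first pattern is 133 genes called alike in all 3 comparisons with PBS, 78 higher and 55 lower, of which 73.7% were pseudogenes against 7.55% of tested genes (Fisher's exact test, p = 2.79e-81). The parents of 11 of the pseudogenes had a median change of 0.0391 (SD 0.240) in the direction of a pseudogene that itself changed by 3.92. These parents had mean levels of 423 to 2458 CPM, and the pseudogenes 0.319 to 9.79 CPM. Reads moved between them could hardly shift a parent. Stable parents therefore cannot tell such reassignment from a change of the pseudogenes themselves. Whether reads of near-identical copies were assigned differently in the PBS libraries stays open. Over protein-coding genes the smallest rho of GC content with the change was 0.307, in line with a trend of library making. Against GC content as the whole cause of the 133 calls, 131 of these genes have a GC value, and a correction that took rho to 0.0291 or less left a median of at least 98.2% of their log2 change in each comparison (5th percentile at least 63.5%) and 106 of the 133 called alike. It ended calls of 24 genes with NTEVs, 11 with DNase-treated ATEVs and 9 with ATEVs. Their median absolute change went from 1.93 (median SE 0.317) to 1.86 (SE 0.315), from 1.30 (SE 0.230) to 0.97 (SE 0.202) and from 0.86 (SE 0.125) to 0.50 (SE 0.124), so smaller changes ended calls with ATEVs and DNase-treated ATEVs, where a part played by GC content stays open for these genes, while with NTEVs the medians moved little and what ended the calls was not tested. Ribosomal RNA reads as a cause stay open too, since the 3 tested loci that resemble ribosomal RNA went both ways (with ATEVs Gm26917 by log2 1.16 and Gm15564 by -2.95, both chosen after their values were seen), so that their median, -0.0859 in the EV group where it was highest, decides nothing. The labels name no batch, so a batch of the PBS libraries and a response to any EV cannot be told apart.

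The next pattern is the rise of antigen presentation and interferon-induced genes with ATEVs. Carry-over of T cells or their RNA is argued against by the sum of Ptprc, Cd3d, Cd3e, Cd3g, Cd2, Lck and Trac, whose larger difference from PBS in an ATEV library was -0.153 CPM, most of it Lck and Trac with a level in all groups, while Cd3d, Cd3e, Cd3g and Cd2 had 0 counts in both ATEV libraries. Transcripts of Ifng, Ifnb1 and the Ifna and Ifnl genes at harvest are argued against by 0 counts over these 18 genes in both ATEV libraries, which allows up to 0.0344 CPM and does not cover earlier expression. For part of the pattern, a soluble factor that DNase pretreatment left untouched is argued against by the fall after pretreatment of the interferon gamma-induced (median -4.69), class I (-2.08) and class II lists (-7.67), with 32 of 32, 21 of 25 and 10 of 11 members below untreated ATEVs in both libraries. For type I interferon-stimulated genes it stays open, as their median fell by 0.997 with 37 of 50 members below and stayed 2.11 above PBS. It stays open that Ifne, another interferon gene, may contribute. Ifne rose by log2 2.42 with ATEVs against PBS (edgeR adjusted p = 0.0373) on low counts, 22 and 18 against 4 and 3. Against PBS it differed by log2 1.42 with NTEVs and 2.33 with DNase-treated ATEVs (edgeR adjusted p 0.209 and 0.0541). Between DNase-treated and untreated ATEVs it differed by -0.09 (edgeR adjusted p = 0.986), so Ifne did not follow the fall of the class I and class II lists. It also stays open that EV-DNA may carry the response, and that a factor may have been removed or inactivated during pretreatment, whose further handling is not described.

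The last pattern is 150 genes other than pseudogenes that were higher than PBS with both ATEVs and DNase-treated ATEVs, with median log2 changes of 2.82 and 2.77, and 0.998 with NTEVs. If the PBS libraries standing apart were the cause, NTEVs should show most of it. Since noise of the PBS libraries that chose the genes would raise all 3 comparisons, genes were chosen anew, at least 1 log2 unit above PBS with both on libraries of 1 number, and measured in those of the other. The NTEV median was 59.3% of that with DNase-treated ATEVs over 115 genes chosen on libraries 1 (1.06 against 1.78) and 64.0% over 518 chosen on libraries 2 (0.28 against 0.44), between the bounds for and against, which were set after such values had been seen, so this cannot be told apart from a response to EVs that resists DNase. A weaker dose of the same response would place the NF-kB list lower after pretreatment, whereas its median was 0.38 higher, but fry gave an adjusted p of 0.132 and decided neither way.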
